A study of Homo sapiens with 21 samples.

How the data were processed

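The study sequenced RNA from liver organoids grown from H9, an established human embryonic stem cell line. Per the labels' protocols, total RNA was extracted with the RNAiso Plus kit and libraries were made with the NEBNext Ultra RNA kit, which is not stated to mark the strand. The labels give 3 experiments with 7 groups of 3 libraries, 21 in all, and each library was placed in its group by its title.

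The authors deposited 1 table per experiment with a whole-number count per gene and library, not normalised. Whole numbers with library totals that differ, per the file headers and values, mark them as raw counts. The submitters' processing notes name GRCh38 as the genome build and DESeq2 as a tool, with no version. The aligner, the counting program, the gene annotation and the strand setting are not given in the sources used here. No column of per-sample values was left unused. The HB-org and P-hep-org tables each held 36601 gene identifiers, of which 34670 carried a gene name in the reference tables. The FFA table held 37438 identifiers, of which 34879 were named. That table lacks several list genes, among them F9, UTF1, CER1, GSC, SLCO1B3, CYP4A11, CIDEB, CRP, SOX1 and NKX6-1, which were not analysed here in the FFA experiment. Coordinates come from GENCODE release 29 on GRCh38.

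Gene counts were fitted with edgeR 4.0.16 in R 4.3.3. Genes were kept with filterByExpr (minimum count 10, minimum total count 15), libraries were scaled with TMM factors, and groups were compared with the quasi-likelihood F test. Adjusted p-values are Benjamini-Hochberg values over the genes tested in a comparison, with a threshold of 0.05. The 6 HB-org libraries and the 6 P-hep-org libraries were fitted separately. The 9 libraries of the FFA experiment were fitted together and so share 1 estimate of the spread. The 5 comparisons were ATT against control in HB-orgs, ATT against control in P-hep-orgs, FFA against control, FFA plus ATT against FFA, and FFA plus ATT against control. Whether the ATT effect differs between P-hep-orgs and HB-orgs was tested as an interaction over the 12 libraries of both tables joined by gene. Stage and table cannot be told apart there, although each stage has its own controls. Log2 fold changes are followed by their standard error. Levels are CPM, the deposited counts as a share of the library's total scaled by its TMM factor, given as mean ± SD over 3 libraries.

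A set of 34 gene lists was tested with camera from limma 3.58.1 on the edgeR fit, with a preset correlation between genes of 0.01. Lists with at least 5 tested members entered, and their p-values were adjusted over the lists of a comparison. As an alternative the correlation was estimated for each list. The lists cover the following groups: plasma proteins, liver transcription factors, fetal liver genes, pluripotency genes, endoderm genes, phase I and phase II drug metabolism, bile acid synthesis and transport, urea cycle and amino acid catabolism, gluconeogenesis, fatty acid synthesis, cholesterol synthesis, fatty acid oxidation, lipid droplets, targets of NRF2, ATF4 and p53, endoplasmic reticulum chaperones, heat shock proteins, heme and iron handling, inflammation, acute phase proteins, interferon-stimulated genes, mitosis, DNA replication, hypoxia and glycolysis, mitochondrially encoded and nuclear-encoded respiratory chain genes, extracellular matrix, cholangiocyte, endothelial, macrophage, neural, and intestinal or pancreatic genes. Several genes belong to more than 1 list, and a hepatocyte also expresses members of the cholangiocyte, matrix, macrophage and intestinal lists.

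The genes named in the text follow a rule. In each comparison it takes the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold, with a mean of at least 2 log2 CPM and with all treated libraries on 1 side of all the comparison's other libraries. Names that are only identifiers were passed over, as were XIST and Y-linked genes. It also takes up to 4 tested members of each list described, by smallest adjusted p, and a panel of 15 genes whatever their p-value. Some results that the rule names are not reported here. Designs, lists, the rule and most alternatives were fixed before the data were examined.

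The alternatives were DESeq2 1.42.0, median-of-ratios factors, scaling by total counts only, no filter, at least 1 CPM in 3 libraries, a log2 fold change of at least 1, the replicate number as a block, the 6 libraries of a pair of groups alone, and each library left out in turn. Added after the data were seen were per-library offsets for transcript length and GC content (loess, span 0.5) and a fit without the 2 libraries that had an excess of genes at 0.

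The procedure was tested on simulated counts drawn from the means and sizes of the real libraries, with 200 genes changed and the plasma protein list raised 1.5-fold. The 200 genes were drawn from those above a minimum mean count. Of genes changed 1.5, 2 and 4-fold, the test recovered 56.7%, 73.1% and 92.4% at the settings of the HB-org comparison (14057 genes). The P-hep-org comparison gave 53.7%, 70.2% and 93.9% (17627 genes). FFA against control gave 82.1%, 95.5% and 100% (16118 genes), FFA plus ATT against FFA gave 83.6%, 98.5% and 100% (16021 genes), and FFA plus ATT against control gave 88.1%, 100% and 100% (16050 genes). The interaction test recovered 32.8%, 50.8% and 84.9% (18592 genes). Between 0.0435% and 0.108% of unchanged genes were called, which made up 4.55% to 7.59% of the calls. Of 29 to 32 lists that were not shifted, 1 to 3 were called in each of the 5 comparisons. A simulated trend with transcript length and no other change in the FFA comparison called 6364 of 17020 genes, and 2 after the offsets.

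Counts of reads were taken as deposited. Reads from near-identical gene copies, from overlapping genes and from antisense pairs may have been split or mixed by the counting, so such genes are given as uncertain. No intervals for counting error are given, because the spread between libraries already contains it.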

Results

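RNA was sequenced from organoids grown from H9, with and without artemisitene (ATT), a compound of the artemisinin family. In the first experiment organoids called HB-orgs, labelled differentiation day 6, were compared with and without ATT, and in another the same was done in more mature organoids called P-hep-orgs. The third experiment held P-hep-orgs as control, with FFA to bring about steatosis, the storage of fat in liver cells, and with FFA plus ATT. The labels spell out neither HB, P-hep nor FFA. Each of the 7 groups had 3 libraries. Deposited counts summed to 16180978 to 19237398 per library in the HB-org experiment and 72642800 to 95994294 in the P-hep-org experiment. In the FFA experiment they summed to 13059385 to 14284036 in controls, 19072705 to 19862732 with FFA and 17313558 to 19911795 with FFA plus ATT. The labels call the replicates biological without saying what separated them, so p-values measure the spread between these samples. Fold changes below are log2 values ± SE from 3 libraries against 3, with Benjamini-Hochberg adjusted p-values of the edgeR test. CYP7A1, which encodes the first enzyme of bile acid synthesis, had too few counts to be tested in any comparison.

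Among the libraries, HB-org ATT replicate 2 had 22416 genes at a count of 0, against 15977 to 16277 in the 5 others of its experiment. P-hep-org ATT replicate 1 had 19640, against 12789 to 13356 in the others. Of genes with 20 to 200 counts in the sister ATT libraries, 12.5% and 20.3% were at 0 in these libraries.

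**Figure D1:**
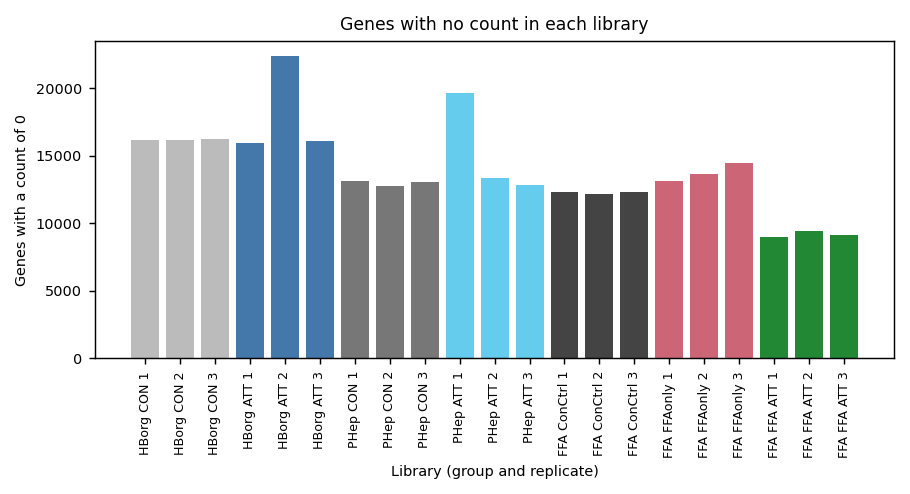
Number of genes with a count of 0 (vertical axis, from 0) in each of the 21 libraries, 1 bar per library, coloured by group. HB-org ATT replicate 2 (22416) and P-hep-org ATT replicate 1 (19640) stand above the other libraries of their experiments, and the FFA plus ATT libraries are lowest (8998 to 9461).

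The HB-org comparison asks what ATT does in organoids at differentiation day 6. All 17 tested hypoxia and glycolysis genes fell with ATT, also 17 adjusted over the list alone, with a list median of -1.54 (camera adjusted p = 7.37e-128). EGLN3, a prolyl hydroxylase that senses oxygen, fell by 2.51 ± 0.057 (adjusted p = 6.98e-08), and NDRG1, BNIP3 and the glycolytic enzyme gene PGK1 had fold changes of -1.68 ± 0.034, -1.65 ± 0.034 and -1.23 ± 0.025. CA9, a carbonic anhydrase induced in low oxygen (ENSG00000107159, GRCh38 chromosome 9, 35673856 to 35681159), fell from 147 ± 10.4 to 13.7 ± 3.23 CPM (SD, n = 3), or by 3.42 ± 0.14. The largest rises included the metallothionein genes MT1H (2.69 ± 0.24), MT1G (2.02 ± 0.16), MT1F (1.61 ± 0.28) and MT2A (1.53 ± 0.12), whose products bind zinc and copper, although near-identical family members can share reads. The zinc transporter genes SLC30A2 (1.72 ± 0.32) and SLC39A8 (1.59 ± 0.21) rose too, as did MFAP3L (1.56 ± 0.21), KCTD12 (1.497 ± 0.17), FAM222A (1.56 ± 0.29) and SLC49A3 (1.51 ± 0.26).

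The largest falls in HB-orgs were in LGALS1 (-4.95 ± 0.61), SCUBE1 (-4.91 ± 0.68) and TFF1, a mucosal trefoil peptide (-4.57 ± 0.61), all below 1 CPM on average with ATT. TFF3, IGFBP6, DUOXA2, SPAG4 and RNF186 fell by 3.07 to 3.32. CEACAM7 fell by 3.30 ± 0.73 (adjusted p = 0.00991), a call that was lost without control 1 (0.0502), control 2 (0.0561) or control 3 (0.0534).

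PLIN2, which coats lipid droplets (ENSG00000147872, chromosome 9, 19108375 to 19149290), fell by 1.06 ± 0.035 in HB-orgs with ATT (adjusted p = 3.58e-07). In the cholesterol synthesis list 15 of 23 genes fell and 1 rose (16 and 1 adjusted over the list alone; median -0.38, or -0.28 under total-count scaling, adjusted p = 3.81e-08), with INSIG1 at -1.41 ± 0.10 and MSMO1 at -1.05 ± 0.039. In the lipid droplet list 4 of 16 fell and 1 rose (5 and 1 adjusted over the list alone; adjusted p = 0.00147), led by HILPDA at -2.17 ± 0.084, and this list had a median of -0.20, or -0.10 under total-count scaling, and adjusted p = 0.213 with an estimated correlation. Fatty acid synthesis genes, with 6 of 19 lower and 2 higher (6 and 3 adjusted over the list alone; adjusted p = 0.132), and fatty acid oxidation genes (0.0587) were not past the threshold as lists. Of 18 ATF4 stress targets 10 fell and 1 rose (13 and 1 adjusted over the list alone; median -0.36, adjusted p = 1.24e-07), including DDIT4 at -1.70 ± 0.042 and TRIB3 at -1.61 ± 0.12. In the cholangiocyte list, whose keratins many epithelia share, 5 of 14 fell and 3 rose, the same adjusted over the list alone (median -0.51, adjusted p = 9.72e-07). KRT7 was at -1.59 ± 0.047 and KRT19 at -0.91 ± 0.031. Of 5 macrophage genes CD68 (-1.43 ± 0.066), a lysosomal protein gene, and LYZ (-0.40 ± 0.079) fell, also 2 adjusted over the list alone (adjusted p = 0.0179, and adjusted p = 0.213 with an estimated correlation).

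All 13 mitochondrially encoded genes rose in HB-orgs, also 13 adjusted over the list alone (median 0.63, adjusted p = 4.67e-11), with MT-ATP6 at 1.00 ± 0.10; the list had adjusted p = 0.225 with an estimated correlation. Of 19 DNA replication genes 10 rose and 1 fell (11 and 1 adjusted over the list alone; adjusted p = 0.00147, and adjusted p = 0.107 with an estimated correlation), with MCM7 at 0.37 ± 0.039. Of 12 heat shock genes 7 rose and HSPB1 fell by 0.78 ± 0.079, the same adjusted over the list alone (adjusted p = 0.00172, and adjusted p = 0.26 with an estimated correlation). HSPH1 rose by 0.88 ± 0.059. Of 23 NRF2 antioxidant targets 9 rose and 3 fell (10 and 4 adjusted over the list alone; adjusted p = 0.00737, and adjusted p = 0.225 with an estimated correlation), with AKR1B10 at 1.11 ± 0.079 and AKR1C1, whose paralogs share reads, at 0.91 ± 0.086.

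Hepatocyte genes in HB-orgs moved both ways. Of 20 plasma protein genes 4 rose and 8 fell (4 and 9 adjusted over the list alone; median -0.15, adjusted p = 0.575). The median was -0.05 under total-count scaling and -0.06 after length and GC offsets. CPS1, which starts the urea cycle, rose by 0.49 ± 0.037, CYP3A4 by 0.79 ± 0.14 and the proliferation marker MKI67 by 0.44 ± 0.052, while HNF4A fell by 0.29 ± 0.041 and COL1A1 by 1.21 ± 0.18. AFP rose by 0.20 ± 0.046 (adjusted p = 0.0112), a call lost without control 2 (0.0664), ATT 1 (0.0504) or ATT 3 (0.0519), and CPT1A by 0.50 ± 0.11 (0.00908), lost without control 2 (0.0514). ALB (0.23 ± 0.10, adjusted p = 0.129) and PDK4 (0.40 ± 0.14, 0.0625) were not past the threshold, but passed without ATT 2 (0.00437 for each) and under total-count scaling (0.33, 0.0322, and 0.50, 0.0227). NQO1 (-0.14 ± 0.047, 0.0513) passed without ATT 2 (0.0236) or ATT 3 (0.0497), with DESeq2 (0.0071), with median-of-ratios factors (0.0347) and after length and GC offsets (0.041). FASN (0.05 ± 0.038, 0.422) and HMOX1 (0.14 ± 0.064, 0.137) were not past it but passed under total-count scaling (0.15, 0.0131, and 0.25, 0.0212), and HMOX1 also passed after length and GC offsets (0.22, 0.0422). TTR (-0.05 ± 0.070, 0.644, and 0.05 under total-count scaling) was not past it. The other 21 lists tested had adjusted p-values from 0.0587 to 0.964. Of these, phase I enzymes passed without ATT 1 (0.0345) or after length and GC offsets (0.0429), fatty acid oxidation and endoplasmic reticulum chaperones without control 2 (0.0373 and 0.0403) or control 3 (0.0387 and 0.0404), and p53 targets without control 2 (0.0477). The median and the test differed in sign for endoderm (-0.30), fetal liver (0.01) and heme and iron genes (0.06).

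In all, 4146 of 14452 genes passed in HB-orgs, 1928 higher and 2218 lower, and 453 of them had an absolute log2 fold change of at least 1 (89 higher, 364 lower). Under total-count scaling, which moved the median of all genes from -0.0042 to 0.098, 65.3% of the called genes were higher rather than 46.5%. The groups did not overlap for 48.1% of genes, against 10% by chance. Without HB-org ATT 2, 7106 genes passed, and without control 1, 2 or 3, 2677, 2604 and 2702 did.

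The P-hep-org comparison asks whether ATT furthers maturation, and its changes were small: 26 of 1469 called genes had an absolute log2 fold change of at least 1. ALB (ENSG00000163631, chromosome 4, 73397114 to 73421412) rose by 0.35 ± 0.018 (adjusted p = 3.6e-05), from 2766 ± 36.8 to 3532 ± 60.5 CPM (SD, n = 3). CYP3A4 rose by 0.33 ± 0.036, PDK4, which restrains glucose oxidation, by 0.37 ± 0.037, and HNF4A by 0.15 ± 0.022. TTR, another plasma protein gene, fell by 0.55 ± 0.017 (4.92e-06), and the plasma protein list was mixed, with 5 of 21 higher and 4 lower (6 and 6 adjusted over the list alone; adjusted p = 0.752). AFP was at -0.00 ± 0.013 (0.974), and 0.02 under total-count scaling, in organoids where it took 6.88% of control counts. The largest rises included CYP2C8, a drug-metabolising enzyme (1.13 ± 0.12), TGFA (1.02 ± 0.14), PPP1R1A (0.95 ± 0.076), CYP26A1, which degrades retinoic acid (0.86 ± 0.091), the glucose transporter SLC5A1 (0.81 ± 0.058) and PALM3 (0.81 ± 0.083). The largest falls included the WNT inhibitor DKK1 (-1.37 ± 0.090), sucrase-isomaltase SI (-1.31 ± 0.099), SPOCK2 (-1.24 ± 0.11), LGALS14 (-1.20 ± 0.090), LAMA4 (-1.10 ± 0.083), SLC7A5 (-1.09 ± 0.17), INHA (-1.07 ± 0.15) and NEBL (-1.04 ± 0.12). SLX1B (-3.23 ± 0.47) has a near-identical copy, so its value is uncertain.

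Endoplasmic reticulum chaperones fell in P-hep-orgs with ATT: 10 of 16 tested were lower and 0 higher by the edgeR test at an adjusted p under 0.05 (12 and 0 adjusted over the list alone; median -0.20, adjusted p = 9.34e-14). HSP90B1 was at -0.32 ± 0.017 and HSPA5, the main chaperone of that compartment, at -0.23 ± 0.017. This list alone also passed with an estimated correlation (0.0341). Of 17 hypoxia genes 9 fell and 1 rose (11 and 1 adjusted over the list alone; median -0.16, adjusted p = 1.81e-09, and adjusted p = 0.193 with an estimated correlation), with P4HA1 at -0.47 ± 0.025 and HK2 at -0.44 ± 0.027. ATF4 targets fell, 3 of 17 (7 lower and 2 higher adjusted over the list alone; adjusted p = 0.00262, and adjusted p = 0.292 with an estimated correlation), with MTHFD2 at -0.97 ± 0.10 and ATF3 at -0.55 ± 0.051. Of 16 p53 targets 3 fell (5 adjusted over the list alone; adjusted p = 0.00156, and adjusted p = 0.236 with an estimated correlation), with GDF15 at -0.45 ± 0.045. Of 16 matrix genes 5 fell and 1 rose, the same adjusted over the list alone (median -0.40, adjusted p = 0.000778, and adjusted p = 0.148 with an estimated correlation). COL4A1 was at -0.43 ± 0.037 and LUM at -0.38 ± 0.031, while LOX, which cross-links collagen, rose by 0.30 ± 0.034.

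Metabolic lists rose slightly in P-hep-orgs. Of 24 NRF2 targets 6 rose (10 higher and 1 lower adjusted over the list alone; adjusted p = 2.5e-05, and adjusted p = 0.122 with an estimated correlation), with AKR1B10 at 0.63 ± 0.059 and OSGIN1 at 0.32 ± 0.045. Of 16 urea cycle and amino acid genes 7 rose, also 7 adjusted over the list alone (adjusted p = 0.00134, and adjusted p = 0.236 with an estimated correlation). Of 23 fatty acid oxidation genes 5 rose, also 5 adjusted over the list alone (adjusted p = 0.00335, and adjusted p = 0.34 with an estimated correlation), with HADH at 0.30 ± 0.034 and VNN1 at 0.27 ± 0.029. Fatty acid synthesis (4 of 19 rose; 5 higher and 1 lower adjusted over the list alone; adjusted p = 0.00187, and adjusted p = 0.193 with an estimated correlation) and cholesterol synthesis (3 of 23 rose; 6 adjusted over the list alone; adjusted p = 0.00134, and adjusted p = 0.169 with an estimated correlation) had medians of 0.09 and 0.08. CYP51A1 of the latter was at 0.21 ± 0.024. Of 31 nuclear-encoded respiratory chain genes 5 rose, also 5 adjusted over the list alone (adjusted p = 0.00574, and adjusted p = 0.443 with an estimated correlation), a call lost without ATT 3 (0.0503).

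Several P-hep-org calls were lost when 1 library was left out. MT2A (-1.07 ± 0.17) was lost without control 2 (0.0586), WNT9B (1.13 ± 0.19) without control 1 (0.0687) or 3 (0.0628), CST1 (1.12 ± 0.18, with close paralogs) without control 1 (0.0548) or 2 (0.0575), and PNMT (1.06 ± 0.19) without control 1 (0.0701) or 3 (0.0689). GTF3C2-AS2 (0.82 ± 0.18), antisense to another gene and so uncertain here, was lost without any 1 control or ATT 3 (up to 0.125). PLIN2 (0.15 ± 0.029) was lost without any 1 control (up to 0.0981), and FASN (0.17 ± 0.038) and CPS1 (0.13 ± 0.026) without any 1 control or ATT 2 (up to 0.161 and 0.113). FASN was lost with the replicate block too (0.0521). The fold changes moved less than the calls. Without the libraries whose removal ended the call they were 0.14 to 0.16 for PLIN2, 0.12 to 0.13 for CPS1, 0.15 to 0.19 for FASN, 1.07 and 1.12 for WNT9B, 1.11 and 1.08 for CST1, 1.04 and 0.97 for PNMT, 0.68 to 0.92 for GTF3C2-AS2 and -0.96 for MT2A. CPT1A (0.12 ± 0.051, adjusted p = 0.246) passed without ATT 1 (0.00677). COL1A1 (-0.22 ± 0.10, 0.259), NQO1 (-0.02 ± 0.034, 0.769), MKI67 (0.75 ± 0.53, 0.494) and HMOX1 (-0.00 ± 0.033, 0.98, and 0.02 under total-count scaling) were not past the threshold.

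Of 18333 genes tested in P-hep-orgs 1469 passed, 656 higher and 813 lower, and the groups did not overlap for 30.5%, against 10% by chance. Under total-count scaling 53.7% of the called genes were higher rather than 44.7%. DESeq2 called 2392 genes, 1159 higher and 1233 lower. Without P-hep-org ATT 1, 4187 genes passed. Without control 1, 2 or 3, 519, 509 and 540 did, and without ATT 2 or ATT 3, 959 and 902. The other 21 lists had adjusted p-values from 0.0535 to 0.981. Liver transcription factors and gluconeogenesis passed without control 2 (0.029 and 0.0337) or ATT 1 (0.0125 and 0.0239), and interferon-stimulated genes without ATT 1 (0.0223). With the replicate block these lists passed as well (0.0431, 0.0497 and 0.0497). After length and GC offsets liver transcription factors and interferon-stimulated genes (0.0377 each) and cholangiocyte genes (0.0341) passed, the last also with a filter of 1 CPM (0.0489). The median and the test differed in sign for gluconeogenesis, inflammation, heat shock, replication, mitochondrially encoded, acute phase and intestinal genes, none of them past the threshold.

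Across both stages, 544 genes passed with the same sign (130 higher, 414 lower) and 183 with opposite signs, against 84.87 and 124 for the same sign if the calls were independent. Of the 183, 63 rose and 120 fell in HB-orgs, against 107 and 98.35 if independent. Leaving out 1 library gave 53 (P-hep-org control 2) to 504 (P-hep-org ATT 1) with opposite signs. With DESeq2 842 had the same sign. Without P-hep-org controls 1, 2 or 3 the first number was 231, 231 and 239, without P-hep-org ATT 3 it was 357, and without P-hep-org ATT 1 it was 1150. The difference of the ATT effects, P-hep-orgs minus HB-orgs, was tested directly in 18592 genes. Of these 2473 passed, 1597 with a positive and 876 with a negative difference. EGLN3 was at -2.51 in HB-orgs and -0.06 in P-hep-orgs, a difference of 2.46 ± 0.065. PLIN2 was at -1.06 and 0.15, a difference of 1.21 ± 0.051. MT2A rose in HB-orgs and fell in P-hep-orgs, a difference of -2.60 ± 0.21.

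**Figure D2:**
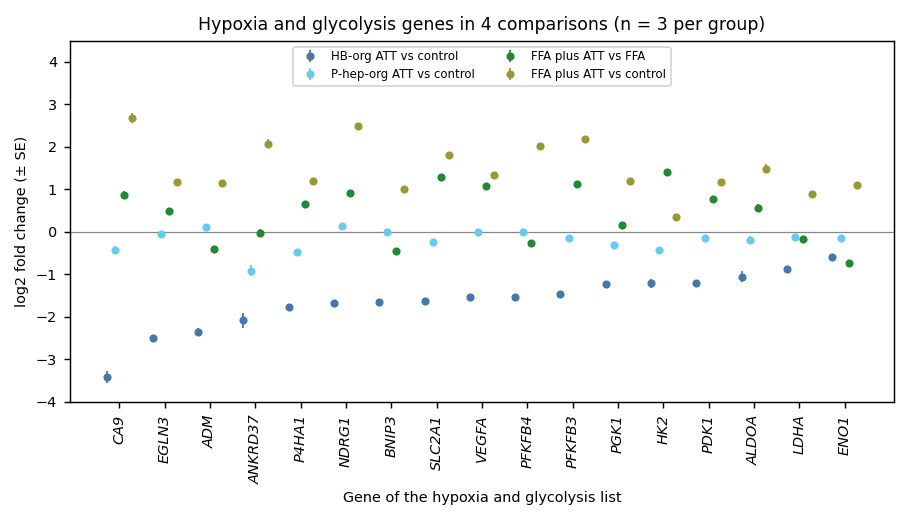
Log2 fold change (vertical axis) of the 17 tested hypoxia and glycolysis genes (horizontal axis) in 4 comparisons, points with bars of ± SE, 3 libraries per group. All 17 were lower with ATT in HB-orgs (median -1.54) and all 17 higher with FFA plus ATT than in the controls of that experiment (median 1.21).

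FFA against control asks what the lipid challenge changed. Plasma protein genes rose with FFA: ALB by 3.74 ± 0.046, SERPINA1, which encodes alpha-1-antitrypsin, by 2.81 ± 0.044, TTR by 2.90 ± 0.071 and AFP by 3.51 ± 0.038 (adjusted p = 2.44e-27), the last from 0.955% to 7.23% of all counts. PLIN2 rose by 2.65 ± 0.042, from 318 ± 4.01 to 1995 ± 68 CPM (SD, n = 3). In the P-hep-org controls of the other experiment, normalised apart, ALB, TTR and AFP lay nearer the FFA level than that of the controls here, unlike PLIN2. HNF4A, PDK4 and FASN also lay nearer the FFA level there, and CPS1 and CYP3A4 lay above it. Whether these rises reflect FFA or the state of these controls was not tested. The largest rises included S100G, a calcium-binding protein (ENSG00000169906, chromosome X, 16650158 to 16654670), by 5.69 ± 0.12, RBP2 by 4.54 ± 0.096, SLC2A5, a fructose transporter, by 4.28 ± 0.13 and MS4A10 by 4.63 ± 0.13. The bile acid carrier SLC10A1 rose by 5.07 ± 0.10. AVP, AQP10, AQP8, GNRH2 and GSTA1, whose paralogs share reads, also rose, by 4.18 to 4.95. The largest falls were in KRT80 (-5.17 ± 0.35), CYP1B1 (-4.65 ± 0.13), ALDH1L2 (-4.59 ± 0.27), the prostaglandin synthase PTGS2 (-4.53 ± 0.14), the BMP inhibitor GREM1 (-4.34 ± 0.16), ASPM (-4.34 ± 0.28), FER1L6 (-4.26 ± 0.093), STEAP4 (-4.14 ± 0.19) and LRRN1 (-4.07 ± 0.16). POTEF (-4.17 ± 0.33) resembles the actin genes, so its value is uncertain.

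Lipid and energy lists rose with FFA, with the same counts adjusted over the list alone in every list of this comparison that passed. Of 23 fatty acid oxidation genes 20 rose and 1 fell (median 1.52, adjusted p = 2.95e-18), with FABP1, which carries fatty acids in the cell, at 3.11 ± 0.070 and ACAA1 at 2.41 ± 0.064. Of 19 lipid droplet genes 14 rose and 1 fell (median 1.10, 2.25e-05), with HILPDA at 2.44 ± 0.068. Of 23 cholesterol synthesis genes 15 rose and 5 fell (median 0.79, 1.05e-06), with DHCR7 at 2.35 ± 0.052. Of 17 hypoxia genes 16 rose and 1 fell (median 1.04, 1.65e-08), with PFKFB4 at 2.28 ± 0.051 and ENO1 at 1.84 ± 0.051. Of 21 plasma protein genes 18 rose and 2 fell (median 2.70, 4.7e-19), and of 18 inflammation genes 13 fell and 3 rose (median -1.0, 1.41e-05), with the chemokine CXCL5 at -3.86 ± 0.079 and BIRC3 at -1.80 ± 0.042. These 6 lists also passed with an estimated correlation. Under total-count scaling their medians, in the order above, were 0.93, 0.51, 0.19, 0.45, 2.12 and -1.60.

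Other lists rose with FFA with the preset correlation only. Of 31 nuclear-encoded respiratory chain genes 29 rose and 1 fell (median 1.30, adjusted p = 1.25e-10, and adjusted p = 0.137 with an estimated correlation), and of 13 mitochondrially encoded ones 10 rose and 2 fell (median 0.92, 1.41e-05, and adjusted p = 0.105 with an estimated correlation). Under total-count scaling the medians of both lists were 0.70 and 0.33, and after length and GC offsets 0.99 and 0.41. COX6C was at 1.89 ± 0.068 and MT-CO2 at 1.60 ± 0.044. Phase II enzymes and transporters (13 of 19 rose, 1 fell, 1.05e-06), bile acid genes (10 of 14 rose, 2 fell, 1.68e-05), gluconeogenesis (9 of 11 rose, 2 fell, 0.000244) and fatty acid synthesis (12 of 19 rose, 5 fell, 0.00358) each had adjusted p = 0.0549 with an estimated correlation. The medians of phase II and of fatty acid synthesis genes, 0.58 and 0.60, were -0.0045 and 0.01 under total-count scaling. UGT2B7, one of a family with shared reads, was at 2.26 ± 0.058, CYP27A1 at 2.46 ± 0.060, FBP1 at 2.67 ± 0.093 and DGAT2, which makes triglyceride, at 2.65 ± 0.056. Phase I enzymes (9 of 16 rose, 4 fell, 0.00554; adjusted p = 0.0755 with an estimated correlation), liver transcription factors (9 of 16 rose, 4 fell, 0.0335; adjusted p = 0.105 with an estimated correlation) and NRF2 targets (15 of 24 rose, 6 fell, 0.00597; adjusted p = 0.255 with an estimated correlation) had medians of 0.56, 0.42 and 0.57 that were -0.03, -0.17 and -0.02 under total-count scaling. Within them NR1H4 was at 2.45 ± 0.064 and SLC7A11, a cystine importer, at -3.73 ± 0.11. Urea cycle genes rose in 8 of 12 (0.00853, and adjusted p = 0.126 with an estimated correlation). Intestinal genes rose in 4 of 8 and fell in 2 (0.0309, and adjusted p = 0.216 with an estimated correlation), with a median of 0.33 that was -0.27 under total-count scaling, FABP2 at 2.96 ± 0.050 and the mucin gene MUC2 at -2.97 ± 0.090. Matrix genes rose in 11 of 19 and fell in 2 (0.0383, and adjusted p = 0.386 with an estimated correlation), a call lost without FFA 3 (0.0661), with LOX at 2.56 ± 0.057.

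Lists that fell with FFA with the preset correlation only were endoplasmic reticulum chaperones, with 13 of 16 lower and 3 higher (median -0.59, adjusted p = 7.88e-05, and adjusted p = 0.105 with an estimated correlation), and p53 targets, with 11 of 16 lower and 4 higher (median -0.92, 0.00513, and adjusted p = 0.104 with an estimated correlation). The same held for mitosis genes, 15 of 18 lower (median -1.90, 0.00212, and adjusted p = 0.0793 with an estimated correlation), and cholangiocyte genes, 7 of 15 lower and 4 higher (median -0.31, 0.0309, and adjusted p = 0.251 with an estimated correlation). The medians of these lists were lower still under total-count scaling, which moved the median of all genes from 0.03 to -0.56. SEL1L was at -1.75 ± 0.050, GDF15 at -1.85 ± 0.048, TOP2A at -3.15 ± 0.16 and SOX9 at -2.65 ± 0.081. In the panel HNF4A (1.23 ± 0.050), CPS1 (0.98 ± 0.060), CYP3A4 (3.78 ± 0.17), PDK4 (2.06 ± 0.056), CPT1A (1.04 ± 0.060), NQO1 (0.77 ± 0.054), HMOX1 (1.32 ± 0.053) and COL1A1 (1.40 ± 0.067) rose and MKI67 (-2.75 ± 0.14) fell. Under total-count scaling the values that moved by over 1.5 times were HNF4A (0.64), CPS1 (0.40), CPT1A (0.45), NQO1 (0.17), HMOX1 (0.73) and COL1A1 (0.81), and after length and GC offsets CPS1 (1.53) and HMOX1 (0.60). FASN rose by 0.58 ± 0.048 but was at -0.01 under total-count scaling. The other 11 lists had adjusted p-values from 0.106 to 0.82. Of these, fetal liver genes passed without FFA 3 (0.0143) and, upward, after length and GC offsets (0.00594), where heat shock genes (0.000152), ATF4 targets (0.00485) and interferon-stimulated genes (0.0398) passed downward.

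In all, 12141 of 17020 genes passed with FFA, 6228 higher and 5913 lower, 6060 of them with an absolute log2 fold change of at least 1. Under total-count scaling 25.9% of the called genes were higher rather than 51.3%, and the median of all genes was -0.56 rather than 0.03. The 10 most abundant genes took 23.8% of counts with FFA and 5.88% in controls. The groups did not overlap for 72.7% of genes, against 10% by chance. Across genes, which are not independent replicates, the fold change also went with transcript length (rho = -0.362) and GC content (rho = 0.385), and after offsets for both 74.2% of the called genes passed in the same direction.

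FFA plus ATT against FFA asks whether ATT relieves the steatosis. Plasma protein genes fell: APOA1, the main protein of high-density lipoprotein, by 3.09 ± 0.083, ALB by 2.36 ± 0.043, AFP by 2.88 ± 0.037 (adjusted p = 1.3e-25), SERPINA1 by 2.10 ± 0.043 and TTR by 2.34 ± 0.070. The largest falls repeated genes that FFA had raised, S100G (-5.76 ± 0.12), RBP2 (-4.16 ± 0.093) and GSTA1 (-4.56 ± 0.061), with CYP3A4 (-4.27 ± 0.17), AKR1B10 (-4.25 ± 0.12), SLC5A1 (-4.14 ± 0.089), C6 (-3.99 ± 0.17), TMIGD1 (-3.96 ± 0.087), PON1 (-3.69 ± 0.17) and FABP6 (-3.67 ± 0.11). KRT80 (5.09 ± 0.35), CYP1B1 (4.10 ± 0.13), FER1L6 (3.96 ± 0.093) and STEAP4 (3.62 ± 0.20), which had fallen, rose, as did MMP19 (4.87 ± 0.17), ATP10B (3.70 ± 0.073), PNMA2 (3.71 ± 0.18) and CYP26B1 (3.55 ± 0.081). SPTBN1-AS2 (3.53 ± 0.33) is antisense to another gene and the strand was not recorded, so its value is uncertain. PLIN2 fell by 0.54 ± 0.039 (adjusted p = 8.31e-12) but was at 0.08 under total-count scaling. HNF4A (-0.49 ± 0.049 and 0.13), CPT1A (-0.56 ± 0.057 and 0.07) and COL1A1 (-0.46 ± 0.062 and 0.16) also fell and changed sign under that scaling. CPS1 (-2.16 ± 0.063), PDK4 (-0.80 ± 0.051), NQO1 (-1.15 ± 0.055) and HMOX1 (-0.85 ± 0.051) fell, and under total-count scaling were at -1.54, -0.18, -0.52 and -0.23. After length and GC offsets HMOX1 was at -0.25 and PLIN2 at -0.24. MKI67 rose by 0.89 ± 0.16, or 1.51 under total-count scaling, a call that was lost after length and GC offsets (0.16, adjusted p = 0.413). FASN was at 0.07 ± 0.047 (0.175), but passed in opposite directions under total-count scaling (0.69, 3.85e-12) and after those offsets (-0.12, 0.0153).

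Of the lists that fell with FFA plus ATT, 7 also passed with an estimated correlation, at 0.0436 each, and counts adjusted over the list alone were the same in all lists of this comparison that passed except NRF2 targets. These were plasma proteins (19 of 21 fell, 1 rose, adjusted p = 9.4e-16), phase II enzymes and transporters (15 of 19 fell, 2 rose, 1.44e-15), mitochondrially encoded genes (11 of 13 fell, 2 rose, 2.68e-11), fatty acid oxidation (20 of 23 fell, 1 rose, 3.21e-10), urea cycle genes (9 of 12 fell, 1.05e-05), phase I enzymes (11 of 16 fell, 1 rose, 0.000208) and gluconeogenesis (9 of 11 fell, 2 rose, 0.000314). Their medians lay between -1.07 and -0.46. Under total-count scaling that of phase I enzymes was 0.17 and the others lay between -0.45 and -0.31. HADH was at -2.08 ± 0.054, ASS1, which condenses citrulline with aspartate, at -3.06 ± 0.10 and MT-ATP6 at -2.04 ± 0.046.

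Other lists fell with the preset correlation only. Of 31 nuclear-encoded respiratory chain genes 29 fell and 2 rose (median -1.14, a smaller fall under total-count scaling, adjusted p = 1.01e-11, and adjusted p = 0.127 with an estimated correlation). Of 24 NRF2 targets 16 fell and 5 rose (17 and 5 adjusted over the list alone; 6.08e-07, and adjusted p = 0.0917 with an estimated correlation), with AKR1C1 at -3.46 ± 0.067. Of 8 intestinal genes 6 fell and 1 rose (2.83e-05, and adjusted p = 0.06 with an estimated correlation), with FABP2 at -3.40 ± 0.051. Bile acid genes fell in 11 of 14 and rose in 2 (0.000139, and adjusted p = 0.0664 with an estimated correlation), with SLC10A1 at -2.65 ± 0.078. Of 7 acute phase genes 6 fell (0.00332, and adjusted p = 0.0962 with an estimated correlation), with SAA1, which shares reads with SAA2, at -2.99 ± 0.097. Lipid droplet genes fell in 12 of 19 and rose in 3 (median -0.72, or -0.10 under total-count scaling, 0.0113, and adjusted p = 0.0664 with an estimated correlation), with MTTP, which loads lipid onto apolipoprotein B, at -1.39 ± 0.043 and CIDEC at -1.36 ± 0.054; this call was lost after length and GC offsets (0.0612). Cholesterol synthesis genes fell in 14 of 23 and rose in 8 (0.0269, and adjusted p = 0.102 with an estimated correlation), with a median of -0.28 that was 0.35 under total-count scaling. Liver transcription factors fell in 10 of 16 and rose in 4 (0.0378, and adjusted p = 0.102 with an estimated correlation), with a median of -0.51 that was 0.11 under total-count scaling, and this call was lost with a filter of 1 CPM (0.0537).

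With FFA plus ATT the hypoxia list rose above FFA alone, with 11 of 17 higher and 5 lower (median 0.57, adjusted p = 0.000974, and adjusted p = 0.0664 with an estimated correlation), HK2 at 1.40 ± 0.046 and SLC2A1, a glucose transporter, at 1.30 ± 0.044. Cholangiocyte genes rose in 8 of 15 and fell in 5 (median 0.59, 0.0168, and adjusted p = 0.2 with an estimated correlation), with SOX9 at 2.47 ± 0.080. Of 16 p53 targets 10 rose and 5 fell (0.0412, and adjusted p = 0.199 with an estimated correlation), with GDF15 at 1.65 ± 0.048 and TP53I3 at -1.69 ± 0.081, a list call lost without FFA 1 (0.0625) or FFA 2 (0.0594). The medians of these 3 lists were 1.19, 1.22 and 1.23 under total-count scaling, and 0.48, 0.13 and 0.48 after length and GC offsets. The other 15 lists had adjusted p-values from 0.061 to 0.949. Interferon-stimulated genes passed without FFA 1 (0.0327), 2 (0.0458) or 3 (0.00283), with the replicate block (0.0393) and after length and GC offsets (0.0466), and heme and iron genes without FFA 3 (0.0404). After these offsets ATF4 targets (median 0.74, 0.000757) and inflammation genes (0.67, 0.00365) passed upward and fatty acid synthesis genes (-0.12, 0.0128) downward. The median and the test differed in sign for fetal liver (0.36) and replication genes (-0.01). In all 11687 of 17020 genes passed, 5843 higher and 5844 lower, 4821 of them with an absolute log2 fold change of at least 1. Under total-count scaling 80.1% rather than 50% were higher, with a median of all genes of 0.64 rather than 0.02. The groups did not overlap for 71.5% of genes, against 10% by chance. Fold changes went with transcript length (rho = 0.346) and GC content (rho = -0.309) across genes, and 75.4% of the called genes passed in the same direction after offsets for both.

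Of the genes called in both comparisons, 9416 moved back with ATT, opposite to their FFA change, and 437 moved further. After length and GC offsets 8171 moved back and 602 moved further. Chance favours opposite signs here because both comparisons share the FFA libraries: the covariance of the fold changes was -1.12, against -0.0255 in simulated data without real changes, where 0 of 10 draws by the edgeR test gave an opposite pair of calls (mean 156 at an unadjusted p under 0.05, against 9733 observed). The simulation held only the spread within groups. It cannot address a shift common to the FFA libraries, which alone would give opposite signs. Of the 9416 genes, 3478 (36.9%) still differed from control on the same side, 4582 (48.7%) were not past the threshold and 1356 (14.4%) were past it on the other side. These genes were chosen for moving back. Over all 12141 genes called with FFA, 5534 still differed from control on the same side. All these counts rest on the controls of the FFA experiment, whose ALB, TTR and AFP levels differed from those of the other P-hep-org controls.

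**Figure D3:**
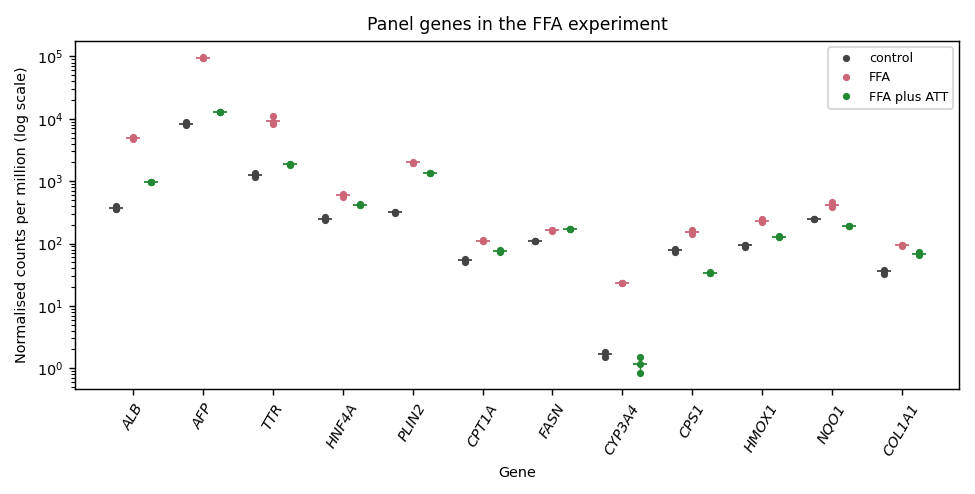
Normalised read counts in CPM (vertical axis, log scale) of 12 panel genes in control, FFA and FFA plus ATT libraries, with points for the 3 libraries of each group and a line for the mean ± SD. AFP and ALB were higher with FFA and lower again with FFA plus ATT, and PLIN2 stayed at 1367 CPM with FFA plus ATT against 318 in controls.

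FFA plus ATT against control asks how organoids given both differed from controls. All 17 hypoxia genes were above control, also 17 adjusted over the list alone (median 1.21, adjusted p = 1.2e-64), with NDRG1 at 2.50 ± 0.047, PFKFB3 at 2.19 ± 0.054 and SLC2A1 at 1.80 ± 0.045. PLIN2 was higher by 2.11 ± 0.041 (1.54e-21), HILPDA by 3.23 ± 0.067, ALB by 1.37 ± 0.042, PDK4 by 1.25 ± 0.056 and AFP by 0.63 ± 0.034. Cholesterol synthesis (18 of 23 higher, 1 lower, the same adjusted over the list alone; 2.66e-09), fatty acid oxidation (19 of 23 higher; 19 and 1 lower adjusted over the list alone; 8.87e-12), lipid droplet (9 of 19 higher, 3 lower, the same adjusted over the list alone; 0.000172) and fatty acid synthesis genes (10 of 19 higher, 4 lower; 11 and 4 adjusted over the list alone; 0.00143) were up. DHCR7 was at 2.08 ± 0.051, ANGPTL4, which inhibits lipoprotein lipase, at 2.49 ± 0.11, FABP1 at 1.71 ± 0.067 and FADS2 at 1.28 ± 0.050. Lower were inflammation genes (13 of 18, with 1 higher; 1.23e-11), interferon-stimulated genes (12 of 17, with 1 higher; 2.66e-09) and endoplasmic reticulum chaperones (14 of 16, with 1 higher; 7.13e-09), each with the same counts adjusted over the list alone, and mitosis genes (14 of 18; 15 adjusted over the list alone; 9.26e-05). CXCL5 was at -2.42 ± 0.067, IFIT2 at -1.56 ± 0.060, HSP90B1 at -0.82 ± 0.037 and TOP2A at -1.77 ± 0.13. These 9 lists also passed with an estimated correlation.

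The largest rises over control were in SLC36A2 (3.79 ± 0.26), PPFIA4 (3.51 ± 0.10), AQP10 (3.40 ± 0.090), GNRH2 (3.31 ± 0.11), NPTXR (3.29 ± 0.12), HAPLN2 (3.02 ± 0.24), ATP8B2 (2.91 ± 0.10) and TNS1 (2.85 ± 0.081), and in SLC2A14 (2.88 ± 0.10), whose reads its paralog SLC2A3 can share. The largest falls were in GREM1 (-3.47 ± 0.14), the chemokine CXCL11 (-3.15 ± 0.097), MUC2 (-3.12 ± 0.087), FGF2 (-2.85 ± 0.12), HEPACAM2 (-2.85 ± 0.16), FCGBP (-2.79 ± 0.096), PDZK1IP1 (-2.77 ± 0.13), LCN2, which binds bacterial iron carriers (-2.74 ± 0.092), ATP6V0D2 (-2.68 ± 0.20) and TDO2 (-2.59 ± 0.19). In the panel HNF4A (0.74 ± 0.050), TTR (0.56 ± 0.067), CPT1A (0.49 ± 0.059), FASN (0.65 ± 0.048), HMOX1 (0.47 ± 0.053) and COL1A1 (0.94 ± 0.067) were higher. CPS1 (-1.18 ± 0.064), NQO1 (-0.38 ± 0.055) and MKI67 (-1.87 ± 0.12) were lower, and CYP3A4 (-0.50 ± 0.24, adjusted p = 0.0876) was not past the threshold but passed without FFA plus ATT 3 (0.0278).

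The remaining lists that passed against control did so with the preset correlation only. Higher were plasma proteins (12 of 21, with 4 lower; adjusted p = 3.99e-06, and adjusted p = 0.151 with an estimated correlation), macrophage genes (4 of 5; 0.0135, and adjusted p = 0.162 with an estimated correlation), matrix genes (5 of 19, with 3 lower; 0.0348, and adjusted p = 0.403 with an estimated correlation) and fetal liver genes (6 of 10, with 4 lower; 0.0349, and adjusted p = 0.149 with an estimated correlation). IGF2, a fetal growth factor, was at 2.26 ± 0.13, GPC3 at 1.27 ± 0.062 and AIF1 at 2.61 ± 0.19. Bile acid genes passed upward (4 of 14 higher, 3 lower; 0.0227, and adjusted p = 0.216 with an estimated correlation) with a median of -0.03, against the sign of the test, as endoderm genes did without passing (-0.13). Lower were phase II enzymes and transporters (11 of 19, with 3 higher; 0.000423, and adjusted p = 0.149 with an estimated correlation), NRF2 targets (13 of 24, with 4 higher; 0.00367, and adjusted p = 0.218 with an estimated correlation), heat shock genes (8 of 12, with 1 higher; 0.00422, and adjusted p = 0.213 with an estimated correlation) and intestinal genes (6 of 8, with 2 higher; 0.00502, and adjusted p = 0.164 with an estimated correlation). So were acute phase genes (3 of 7, with 2 higher; 0.0105, and adjusted p = 0.149 with an estimated correlation), mitochondrially encoded genes (8 of 13, with 2 higher; 0.0122, and adjusted p = 0.298 with an estimated correlation) and urea cycle genes (7 of 12, with 3 higher; 0.0305, and adjusted p = 0.206 with an estimated correlation). p53 targets were lower in 7 of 16 and higher in 1 (0.0349, and adjusted p = 0.188 with an estimated correlation), a call lost with a filter of 1 CPM (0.062). Counts adjusted over the list alone were the same for these lists except phase II enzymes and transporters (4 higher). SAA1 and SAA2, which share reads, were at -2.27 ± 0.099 and -2.37 ± 0.15, ABCB1 at -1.33 ± 0.054 and HSPH1 at -0.97 ± 0.063.

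Of 17020 genes 8442 passed against control, 4044 higher and 4398 lower, 1850 with an absolute log2 fold change of at least 1. The groups did not overlap for 60.2% of genes, against 10% by chance. The other 11 lists had adjusted p-values from 0.157 to 0.899. Over all 5 comparisons, pluripotency, endoderm, endothelial, and heme and iron genes were not past the threshold with all libraries and the preset correlation where they had at least 5 tested members, although heme and iron genes passed without FFA 3 in FFA plus ATT against FFA (0.0404), and neural genes had 2 to 4 tested members and were not tested as a list.

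**Figure D4:**
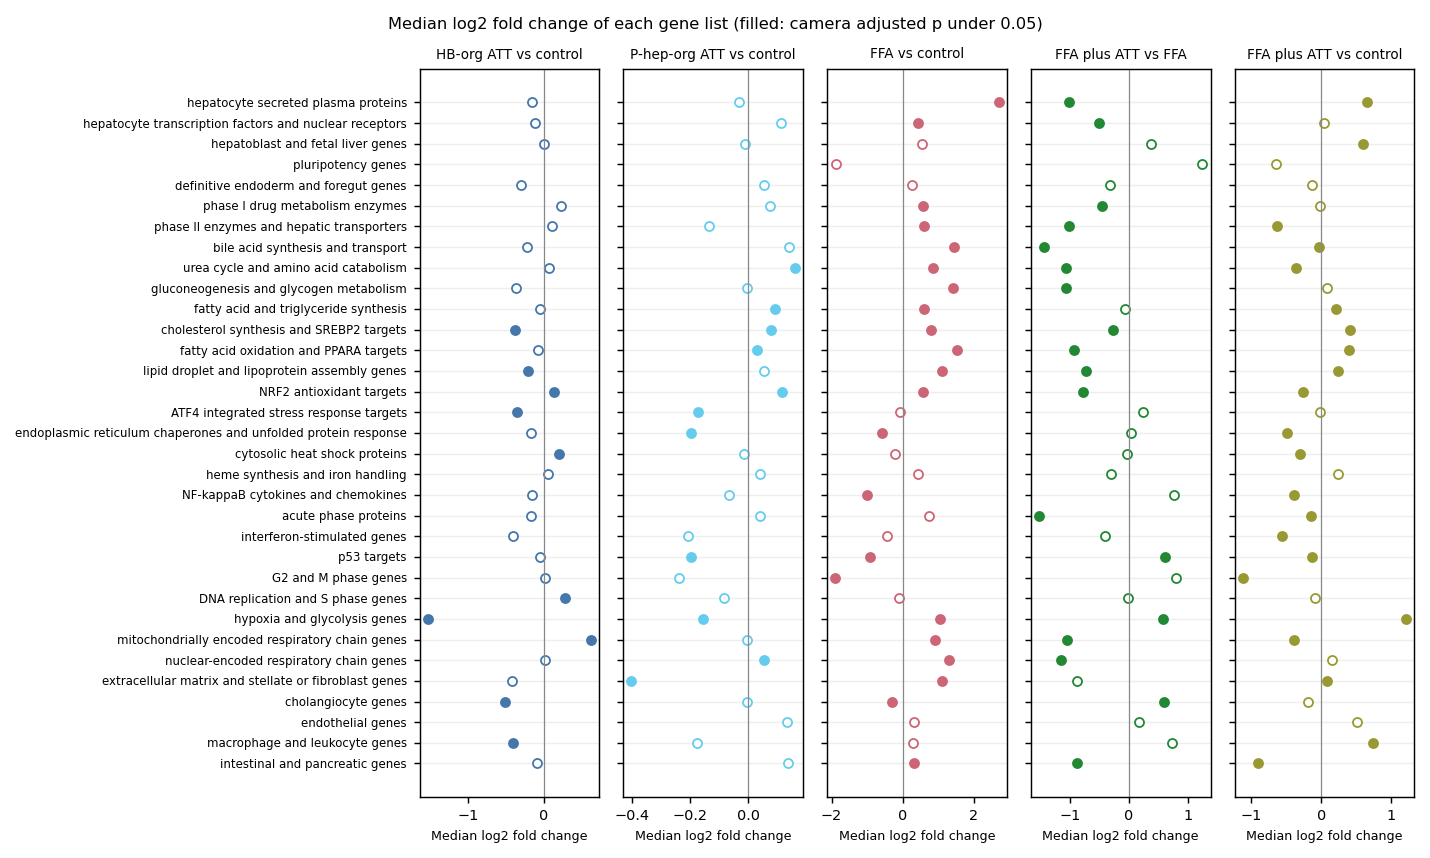
Median log2 fold change (horizontal axis, its scale differing between panels) of 33 gene lists (vertical axis) in the 5 comparisons, with filled points where camera gave an adjusted p under 0.05. Plasma protein genes had medians of 2.70 with FFA, -1.01 with FFA plus ATT against FFA and 0.65 with FFA plus ATT against control.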

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

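The tests of the libraries with an excess of genes at 0, the fit without both of them, the length and GC offsets, and the test of a culture difference behind the hypoxia genes were chosen only after the result was seen.

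The effect of ATT differed between P-hep-orgs and HB-orgs in 71 of the 106 named genes that could be tested, by the edgeR interaction test with adjusted p-values up to 0.0388. Many of these genes were named for a large change or a small p-value in 1 of these stages, so a high share is built in. Over all genes tested it was 2473 of 18592. The values in parentheses are the log2 fold change in P-hep-orgs minus that in HB-orgs. Hypoxia genes fell strongly in HB-orgs and much less or not at all in P-hep-orgs. CA9, for one, was at -3.42 in HB-orgs and -0.425 in P-hep-orgs. Their differences were thus positive, with CA9 (3.00), EGLN3 (2.46), NDRG1 (1.81), BNIP3 (1.63), SLC2A1 (1.39), P4HA1 (1.30), PGK1 (0.93) and HK2 (0.78). Lipid genes gave HILPDA (1.95), INSIG1 (1.57), PLIN2 (1.21), MSMO1 (1.196), FADS2 (0.97), PLIN3 (0.79), CYP51A1 (0.64), FADS1 (0.55) and HMGCS1 (0.46). Among stress genes the difference was positive for TRIB3 (1.67), ATF3 (1.47), DDIT4 (1.45), GDF15 (1.05), HSPB1 (0.95) and HSP90B1 (0.19), and negative for MTHFD2 (-0.82), HSPH1 (-0.64), AKR1C1 (-0.51), AKR1B10 (-0.48) and HSPA8 (-0.45). Other genes that had fallen in HB-orgs gave LGALS1 (4.27), SCUBE1 (4.10), TFF1 (3.98), DUOXA2 (3.07), CEACAM7 (3.03), SPAG4 (2.98), TFF3 (2.88), RNF186 (2.83), IGFBP6 (2.70), CLDN4 (0.90), KRT7 (0.85) and KRT19 (0.65). The difference was negative for the metallothionein genes MT1G (-5.23), MT2A (-2.60) and MT1F (-2.34), while MT1H (-1.82, adjusted p = 0.0984) was not past the threshold. It was also negative for SLC30A2 (-1.47), SLC7A5 (-1.44), SLC39A8 (-1.42) and SLC49A3 (-1.27) and for the mitochondrial genes MT-ATP6 (-1.10), MT-CYB (-0.91) and MT-ND2 (-0.78). Hepatocyte and other genes with a negative difference were SLX1B (-4.44), SI (-2.51), KCTD12 (-2.35), MFAP3L (-1.72), FAM222A (-1.62), DKK1 (-0.64), LUM (-0.53), TTR (-0.49), MCM7 (-0.48), CYP3A4 (-0.46), CPS1 (-0.36) and AFP (-0.20). A positive one was found for PNMT (6.19 ± 1.78), INHA (3.09), LGALS14 (2.47 ± 0.62), LOX (1.45), CD68 (1.40), NAGS (1.13), COL1A1 (0.99), CST1 (0.84) and HNF4A (0.44). LGALS14 and PNMT had too few counts in HB-orgs to be tested there, so the size of their difference is uncertain, and the P-hep-org call of PNMT was lost without control 1 (adjusted p = 0.0701) or 3 (0.0689). In all, 13 of the 71 genes passed in both stages with opposite signs. Among these, the P-hep-org call was lost without control 1 for FADS1 (adjusted p = 0.056), control 2 for MT2A (0.0586), control 3 for FADS2 (0.0563), control 2 or 3 for MSMO1 (0.0525 and 0.0544) and any 1 control for PLIN2 (up to 0.0981). Leaving out 1 library was examined only for genes named in the comparison concerned, so the others were not all checked. Their weakest P-hep-org calls by edgeR were INSIG1 (adjusted p = 0.0426), NDRG1 (0.0245) and HSPB1 (0.0166). The HB-org call of SI had an edgeR adjusted p of 0.0408. Over all genes 2473 passed, and the highest of the other drawn splits gave 2343, so that 1 of 100 splits, the real one, gave as many. That share bears only on whether the groups differ in either stage, and chance was not excluded for the difference between the stages. The 91 splits that mixed the HB-org groups gave at most 2 genes (1415 at an unadjusted p under 0.05, edgeR), since they remove the ATT effect there. The 8 others that kept that grouping gave 1779 to 2343 and are too few for a share under 0.05. The count thus mostly reflects the ATT effect in HB-orgs.

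For the 5 single comparisons the 3 libraries against 3 make 10 splits, too few for a share under 0.05. In each, 1 split, the real one, gave as many genes. In HB-orgs 4146 genes passed and the highest other split gave 0 by edgeR (295 at an unadjusted p under 0.05). In P-hep-orgs the values were 1469 and 0 (510 unadjusted), with FFA 12141 and 0 (237), with FFA plus ATT against FFA 11687 and 0 (206), and with FFA plus ATT against control 8442 and 0 (198).

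In HB-org ATT 2 and P-hep-org ATT 1 many genes with moderate counts in the sister ATT libraries were at 0. A count minimum would leave abundant genes alone, but in genes above 1000 counts their squared deviations from the sisters were 8.18 and 5.45 times those of the sister pair, and a loss of rare transcripts with ATT would reach the sisters, which held at most 1.36% more genes at 0 than the highest control. Few amplified molecules are a candidate explanation: the zeros correspond to 24 and 32.6 reads per molecule and the spread of abundant genes to 35.5 and 62.8, within 2-fold in each library. It was found from the same values and stays a hypothesis. Without both libraries the interaction test passed 5396 genes.

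Short and GC-rich genes were higher in the FFA libraries, with a median log2 fold change of 0.52 in the 10% of genes with the shortest transcripts and -0.81 in the 10% with the longest. A trend with length and GC of the kind the offsets remove is excluded as the whole cause. After them 74.2% of the genes called with FFA passed in the same direction, and the plasma protein list had a camera adjusted p of 2.45e-28. Other differences shared by the FFA libraries were not tested. A part of the changes may still come from such a trend or another bias, because FFA treatment and any difference in library making cannot be separated in these 9 libraries. An effect of FFA itself stays open, untested apart from these.

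The hypoxia and glycolysis list was lower with ATT in HB-orgs (median -1.54). Without HB-org ATT 2 the median was -1.57 and after length and GC offsets -1.58, which excludes both as its cause. A culture difference between the groups other than ATT, such as oxygen supply, and an effect of ATT cannot be told apart, since no group in the design differs in culture alone. The list went the other way with FFA plus ATT against FFA (median 0.57), in other organoids and with FFA present.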

How the results depend on the processing

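The length and GC offsets and the fit without both libraries with an excess of zeros were chosen only after the result was seen.

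Of 3696 values of 336 named genes under the alternatives, 3622 kept their direction and their side of the threshold, 53 lost the threshold, 15 gained it and 6 reversed. Most of the losses, 44, were in P-hep-orgs on leaving out 1 library. The reversals under total-count scaling were FASN with FFA (-0.013), and with FFA plus ATT against FFA HNF4A (0.13), PLIN2 (0.079), CPT1A (0.066) and COL1A1 (0.16), which follows from that scaling moving all genes by 1 amount per library. FASN with FFA plus ATT against FFA was -0.12 after length and GC offsets, and the cause was not tested. Of 1613 values of 162 list results, 1517 were the same, 63 lost the threshold, 33 gained it and 0 reversed by camera. The lists that passed with an estimated correlation numbered 4 of 10 in HB-orgs, 1 of 11 in P-hep-orgs, 6 of 22 with FFA, 7 of 18 with FFA plus ATT against FFA and 9 of 22 against control, and the cause was not tested.

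Requiring an absolute log2 fold change of at least 1 left fewer genes by construction: 453 in HB-orgs, 26 in P-hep-orgs, 6060 with FFA, 4821 with FFA plus ATT against FFA, 1850 against control, 3568 moved back, 506 in the interaction and 3 shared by both stages. DESeq2 called 2392 genes in P-hep-orgs and 842 shared by both stages, and the cause was not tested.

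Leaving out 1 library gave 2604 to 7106 genes in HB-orgs (2677, 2604 and 2702 without controls 1, 2 and 3, and 7106 without ATT 2) and 509 to 4187 in P-hep-orgs (519, 509 and 540 without controls 1, 2 and 3, 959 and 902 without ATT 2 and 3, and 4187 without ATT 1). Shared calls ranged from 231 to 1150 (231, 231 and 239 without P-hep-org controls 1, 2 and 3, 357 without P-hep-org ATT 3, and 1150 without P-hep-org ATT 1). Without both libraries with an excess of zeros the interaction had 5396 genes and 1698 calls were shared. Fewer libraries lower the counts by construction. The rises came only on leaving out HB-org ATT 2, P-hep-org ATT 1 or both. Median squared deviations of HB-org ATT 2 from its sister ATT libraries were 19.2 and 18.8 times counting noise, against 2.14 between the sisters. For P-hep-org ATT 1 they were 34.7 and 36.1, against 5.02. Such a spread within a group raises p-values, so leaving these libraries out can raise the counts. Whether it was the only cause was not tested. In the FFA experiment the counts on leaving out 1 library were 11626 to 12013, 11017 to 11528 and 7341 to 7514 in the order above, with 9044 to 9221 moved back, and the interaction had 1795 to 3223.

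With the replicate number as a block 3384, 1112, 12054, 11590 and 8360 genes and 10, 14, 22, 19 and 22 lists passed in the 5 comparisons, 9345 genes moved back, 2016 passed the interaction and 405 were shared. Deviations of equally numbered libraries had correlations across genes from -0.0366 to 0.0248, which gave no sign that the numbers pair the samples. Counting noise is part of these deviations and lowers such correlations, so a pairing was not excluded. The interaction was not run with length and GC offsets, which were fitted per table. The simulated 1.5-fold changes were recovered in 56.7% of genes in HB-orgs, 53.7% in P-hep-orgs and 82.1% to 88.1% in the FFA experiment. This did not follow depth, since the P-hep-org libraries held the most counts. The common dispersion, a measure of spread beyond counting noise, was 0.0229 in HB-orgs, 0.0544 in P-hep-orgs and 0.00383 in the FFA experiment. The values of HB-orgs and P-hep-orgs include the libraries with an excess of zeros, which spread more from their sisters. The changed genes were above a minimum mean count, so these rates do not bear on genes with few counts. What depth limits was not tested in another way.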

Other observations

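The levels below were picked only after the result was seen, while the overlaps of calls were planned. They are CPM, mean ± SD over 3 libraries, normalised within each table. Their scaling factors were not those of the levels above, so the same gene can differ slightly between both.

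CDX2, a transcription factor of the intestinal epithelium, was at 372 ± 3.54 CPM in HB-org controls, 227 ± 6.21 in P-hep-org controls and 178 ± 8.08 in FFA controls. VIL1, a microvillus protein gene, was at 682 ± 12.4, 882 ± 13.8 and 418 ± 12.2. Over the 7 groups the means of MUC2 ranged from 1.91 to 113, SI from 1.89 to 40.6, LGR5 from 0.0444 to 34.2 and OLFM4 from 0 to 1.36. APOA4, a lipoprotein gene of intestine and liver, was at 58.3 ± 2.64, 5907 ± 85.2 and 7915 ± 295 in these controls, and at 55320 ± 7300 with FFA and 11730 ± 252 with FFA plus ATT. H19, an imprinted fetal transcript, was at 37.0 ± 20.7 in FFA controls, 51.5 ± 7.21 with FFA and 116 ± 60.3 with FFA plus ATT.

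AFP took 6.88% ± 0.071 of counts in the controls of the P-hep-org experiment and 0.955% ± 0.044 in those of the FFA experiment (SD, n = 3), although both are labelled P-hep-org controls. With FFA its share was 7.23% ± 0.13. ALB was at 2763 CPM in the P-hep-org controls, 375 in the FFA controls and 4784 with FFA, and TTR at 6023, 1270 and 9079. MKI67 was at 0.805, 31.0 and 4.42. PLIN2, at 226, 321 and 1930, lay nearer the FFA controls, as did CPT1A, HMOX1, NQO1 and COL1A1. HNF4A (524, 254 and 571), PDK4 (129, 43.4 and 173) and FASN (153, 111 and 158) lay nearer the FFA level. In the P-hep-org controls CPS1 (496, 78.2 and 148) and CYP3A4 (103, 1.70 and 22.4) lay above both other groups. Whether the FFA changes reflect FFA or the state of the FFA controls was not tested. Over 13618 genes the Spearman correlation of group means, across genes, was 0.907 between both sets of controls and 0.975 between the FFA controls and FFA plus ATT. It was 0.909 between the FFA controls and FFA. Between the P-hep-org controls and FFA it was 0.894.

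Changes with ATT in P-hep-orgs tended to oppose those of FFA plus ATT against FFA. Of genes called in both, 1071 had opposite and 242 equal signs (Pearson r = -0.268 across 15423 genes, which are not independent). Opposite signs came in 527 and 544 genes, against 230.9 and 282.7 if the calls were independent. Equal signs came in 61 and 181, against 225.8 and 289.1. A shift common to the FFA libraries would move the second comparison too, so an ATT effect that differs with FFA was not separated from it. SLC5A1 rose by 0.81 ± 0.058 without FFA and fell by 4.14 ± 0.089 with it. In HB-orgs against the same comparison, 1683 signs were equal and 1650 opposite. The libraries with FFA plus ATT held 8998 to 9461 genes at 0, against 12199 to 12353 in their controls and 13180 to 14465 with FFA.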
